A study of Mus musculus with 6 samples.

How the data were processed

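RNA labelled as colon crypt RNA in 6 samples of C57BL/6J mice, 3 of control mice (titled PBS) and 3 of mice gavaged with MBELN for 7 days, was hybridised to single-colour mouse arrays. Per the labels' protocols, total RNA was extracted with Trizol and 90 ng was made into biotinylated cRNA after an Affymetrix protocol. The same label also names an Ion AmpliSeq mouse transcriptome assay, which is a sequencing method, and the sources used here do not resolve this. Transcriptome Analysis Console 4.0 is named in the submitters' processing notes. The method of summarization, background correction and normalization, and the genome build, are not given in the sources used here.

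The authors deposited 1 value per probe set and array, read here as log2 because none was below 0, array medians lay between 4.38 and 4.55, and the highest value was 19.9. That scale is inferred from the values and not stated. Values near 19.9 lie at the top of the scale, so differences that involve them may be understated. The table held 28846 probe sets, of which 6640 were array controls and stayed out of every test. Of the 22206 transcript probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 had none. These gave 19505 genes, 55 of them with more than 1 probe set, of which the set with the highest mean over the 6 arrays stood for the gene in list tests. Symbols were checked through Entrez identifiers against a gene table of assembly GRCm38.p6, which held all 19572 and changed 0 symbols. No coordinates were taken from it. Hspa8, named in advance, was not analysed here because no probe set was paired with that symbol.

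Groups were taken from the sample titles and labels. The comparison of MBELN with PBS used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with statmod 1.5.0 on the deposited values, without covariates, two-sided, with Benjamini-Hochberg adjustment over the 22206 probe sets and a threshold of 0.05. The fit had 4 residual degrees of freedom and 1.66 prior degrees of freedom. Positive differences are MBELN minus PBS. Gene lists were tested with camera at a preset correlation of 0.01 over the 42 of 44 lists that had at least 5 measured members and were fixed before the data were examined. Camera with an estimated correlation and fry were alternatives. A set of 9 tissue marker lists was written after the values had been seen and is described by its values, and its list tests are not given.

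A level for dim probe sets was set per array at the 95th percentile of 1414 olfactory and vomeronasal receptor probe sets, which lay between 3.99 in PBS 3 and 4.44 in MBELN 3. For group means, the same percentile of the means was 4.01 in PBS and 4.15 in MBELN. Where every array of 1 group was below its level, the change is given as at least N-fold, from the brighter group's mean to the mean of those levels. Genes were named by a rule fixed before the data were examined. It takes Ahr, Arnt, Cyp1a1, Cops8 and Hspa8, the 12 largest changes in each direction among genes past the threshold with no overlap between groups and a mean above the dim level, and up to 4 members with the smallest p of each list described. Predicted genes without a proper symbol were counted and not named. Tissue marker genes were named outside this rule, after their values had been seen.

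The hybridisation control probe sets fell into a higher level, with means between 9.79 and 10.09 in PBS 2, MBELN 1 and MBELN 3, and a lower level, with means between 8.43 and 8.98 in PBS 1, PBS 3 and MBELN 2. This level was used as a block, and the fit was repeated within each level with 1 residual degree of freedom. PBS 2 in the higher and MBELN 2 in the lower level are then the lone array of their group, assumed to vary like the others.

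The procedure was tested on simulated data with the probe sets and spread of this comparison, over 22206 probe sets in 5 rounds. It recovered 82.0% of probe sets changed by 8 log2 units, 47.6% of those changed by 4, 6.8% of those changed by 2 and 0% of those changed by 1. With no change, 5.15% of p-values lay under 0.05. The noise was drawn independently for each probe set and array, so deviations that many genes of 1 array share were not simulated. Alternatives were quantile normalization, median centring, a filter on dim probe sets, a trended robust variance model, array weights, a replicate block, each array left out in turn, other thresholds and other choices of probe set. Those on the hybridisation control level and without PBS 2 and MBELN 2 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.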

Results

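Gene expression was measured on 6 single-colour arrays of RNA that the labels describe as coming from colon crypts, the epithelial glands of the large bowel, of C57BL/6J mice. 3 arrays came from control mice, titled PBS. The other 3 came from mice given MBELN, exosome-like nanoparticles prepared from mulberry bark, by oral gavage on 7 days. Arrays are named here by their titles. Each array gave a log2 value for 22206 transcript probe sets. The median value lay between 4.38 in PBS 3 and 4.55 in MBELN 2, and between 50.3% of probe sets in MBELN 3 and 55.2% in MBELN 2 lay above the level of olfactory and vomeronasal receptor probe sets. The labels do not state that each array is a separate mouse, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

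Transcripts of tissues other than colon crypt were abundant in all 3 arrays labelled MBELN. In MBELN 1 and MBELN 3, the median of 15 heart muscle genes was 18.22 and 18.83, against 3.74 to 4.0 in the PBS arrays and 3.68 in MBELN 2. Myh6, the cardiac myosin heavy chain, read 18.8 in MBELN 1 and 19.0 in MBELN 3, and 3.68 in MBELN 2. In the array labelled MBELN 2, the median of 13 neuronal genes was 16.12, against 3.55 to 3.89 in the other 5 arrays, and that of 10 glial genes was 12.30. Syn1, which encodes synapsin 1 of synaptic vesicles, read 16.1 in MBELN 2 and 2.70 and 3.23 in MBELN 1 and MBELN 3. The median of 15 gut epithelial genes was 16.88, 15.83 and 17.45 in PBS 1, 2 and 3 and 4.46, 3.44 and 4.89 in MBELN 1, 2 and 3. The heart, neuronal, glial and gut epithelial lists and the genes named from them were chosen after the values had been seen. Of the 15 heart genes, 3 lay above the receptor probe set level in all 3 PBS arrays, as did 5 of the 13 neuronal, 2 of the 10 glial and 14 of the 15 gut epithelial genes. Lists fixed before the data were examined held 0, 1, 1 and 3 of these genes.

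**Figure D1:**
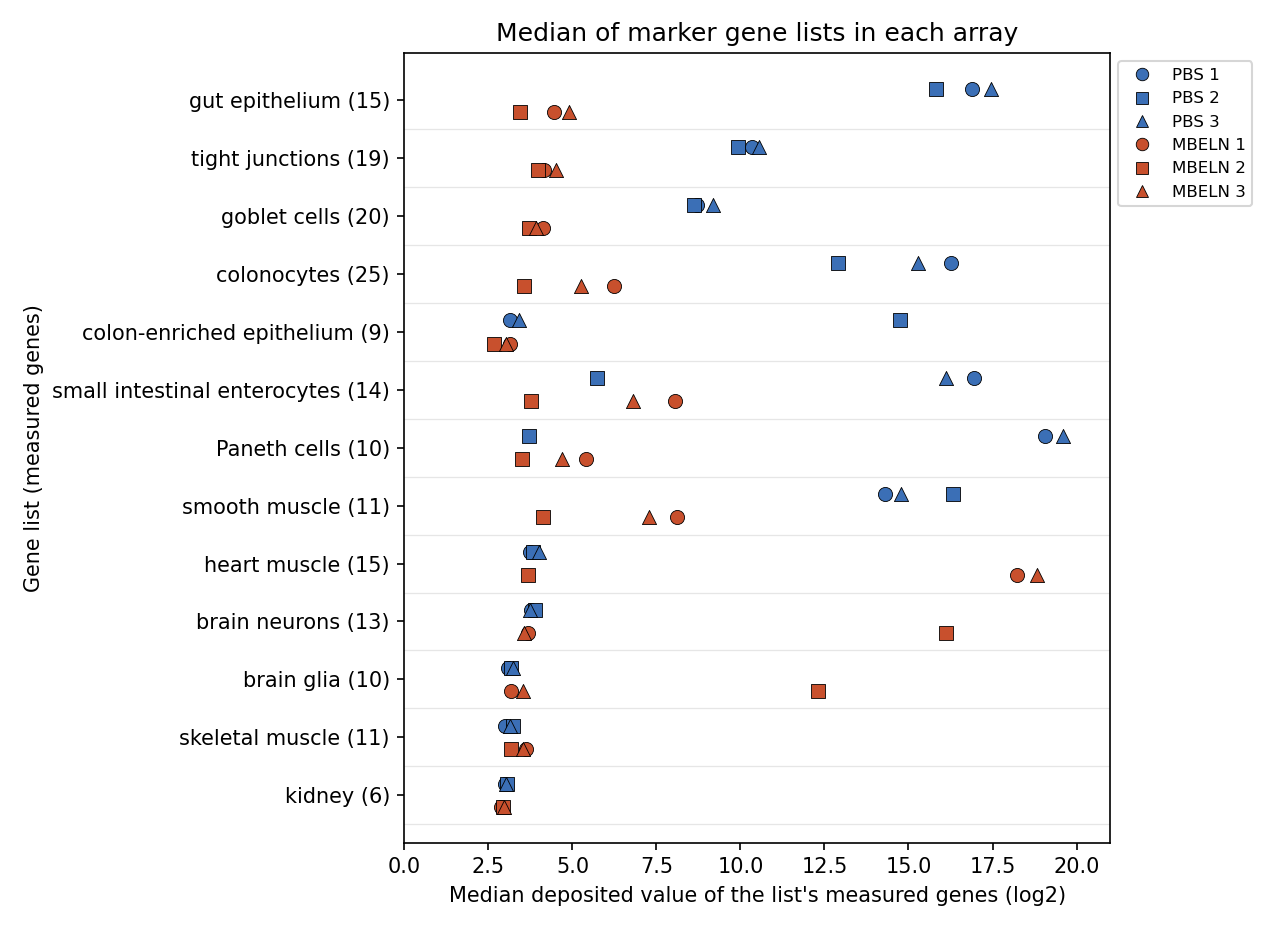
Median deposited log2 value of the measured genes of 13 marker lists in each array, with blue points for PBS and red points for MBELN, and circles, squares and triangles for replicates 1, 2 and 3. Heart muscle genes stood at 18.22 and 18.83 in MBELN 1 and MBELN 3, neuronal genes at 16.12 in MBELN 2, and gut epithelial genes between 15.83 and 17.45 in the PBS arrays.

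The PBS arrays also differed from each other. Paneth cell genes, which encode antimicrobial peptides of small intestinal crypts, had a median of 19.06 in PBS 1 and 19.61 in PBS 3, and of 3.69 in PBS 2. Small intestinal enterocyte genes had a median of 16.96 and 16.11 in PBS 1 and PBS 3, and of 5.72 in PBS 2. The order was the opposite for 9 genes enriched in colon epithelium, a list also chosen after the values had been seen, with 14.74 in PBS 2, 3.13 in PBS 1 and 3.40 in PBS 3. Aqp8, a water channel of colonic surface cells, read 16.1 in PBS 2, 2.71 in PBS 1 and 2.62 in PBS 3. Lists fixed before the data were examined held 7 of these 9 genes. The colonocyte list, fixed in the same way and holding some of them, ran the other way. Its median was 16.28 in PBS 1, 15.27 in PBS 3 and 12.90 in PBS 2. Across probe sets, which are not independent replicates, Pearson's r was 0.983 between PBS 1 and PBS 3 and 0.977 between MBELN 1 and MBELN 3. It was 0.891 and 0.886 between PBS 2 and the other PBS arrays, and 0.663 and 0.662 between MBELN 2 and the other MBELN arrays.

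**Figure D2:**
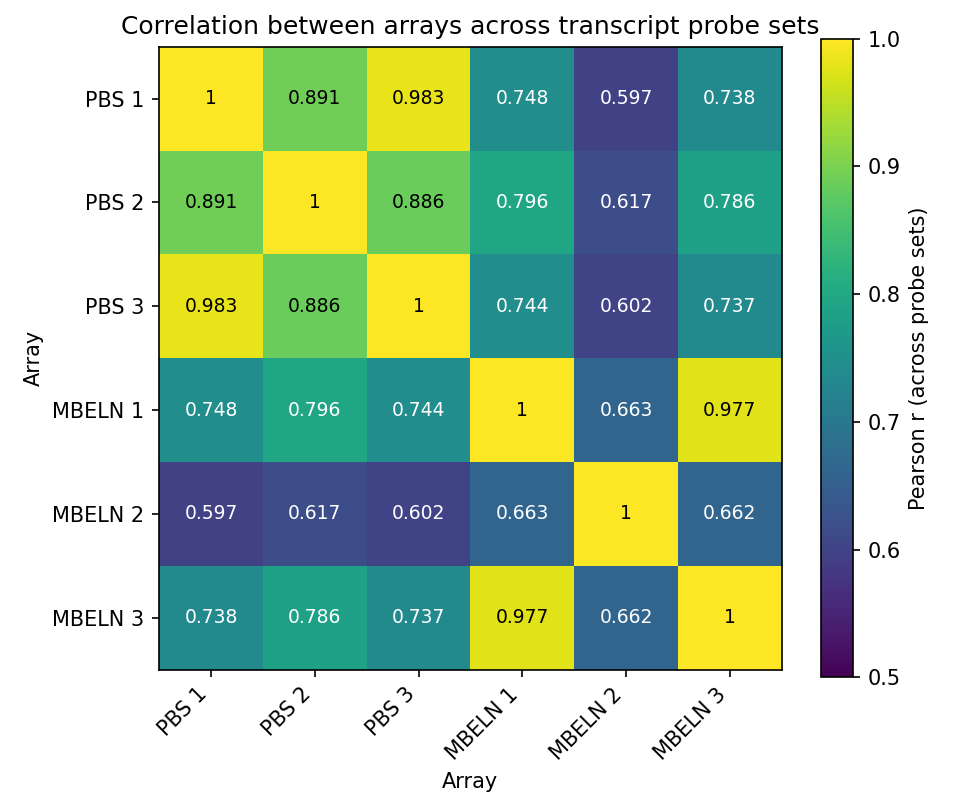
Pearson's r between each pair of the 6 arrays across 22206 transcript probe sets, written in each cell and shown by colour from 0.5 to 1. The pairs PBS 1 with PBS 3 (0.983) and MBELN 1 with MBELN 3 (0.977) had the highest values, and MBELN 2 had 0.597 with PBS 1.

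The series compared MBELN with PBS to find transcripts that differ in colon crypts after the treatment. In the arrays labelled MBELN, genes of the gut epithelium were far lower than in PBS. Slc44a4, a choline transporter family member, read 18.05 ± 0.25 in PBS and 3.43 ± 0.09 in MBELN (log2, SD, n = 3), at least 13720-fold lower. Cdh1, the epithelial cadherin, fell by 13.85 ± 0.48 (log2, SE, n = 3) and Clca1, a goblet cell secretory protein, fell from 19.41 ± 0.66 in PBS to 3.96 ± 1.17 in MBELN (SD), a mean below the receptor probe set level. Eef1a2, the translation elongation factor form of muscle and neurons, rose by 11.46 ± 0.34 (log2, SE, n = 3), and Rcan2, a regulator of calcineurin, rose by 12.72 ± 1.12. With limma and Benjamini-Hochberg adjustment, 1150 of 22206 probe sets passed an adjusted p of 0.05, 315 higher and 835 lower in MBELN. Over all 22206 probe sets, the 3 MBELN values lay on one side of the 3 PBS values in 5629 (25.3%), and chance gives this in 10%. All 1150 were among the 5629. The share of lower probe sets among those past the threshold was 72.6%, and between 81.3% and 86.5% without PBS 1, PBS 2, PBS 3, MBELN 1 or MBELN 3. It was 43.5% without MBELN 2 (2112 higher and 1626 lower), 50.1% with array weights (2870 and 2887) and 50.5% without PBS 2 and MBELN 2 (3354 and 3415), settings in which both counts were larger. The count was 377 without PBS 1, 379 without PBS 3, 501 without MBELN 1, 3738 without MBELN 2 and 447 without MBELN 3. It was 1375 with the level of the hybridisation controls as a block. The count was 4174 within the arrays of higher level, PBS 2 alone against MBELN 1 and MBELN 3, and 7234 within those of lower level, PBS 1 and PBS 3 against MBELN 2 alone, where the lone array is assumed to vary like the others. The level divides the arrays as the marker lists do, so block and within-level values set heart-marked arrays against the colon-marked PBS 2, and the brain-marked MBELN 2 against the PBS arrays with small intestinal markers. With PBS 2 and MBELN 2 both left out, the count was 6769, in a setting chosen after the data had been seen.

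By the difference of the deposited values, the 12 named genes with the largest falls were Clca1, Slc44a4, Guca2a, Tff3, Mep1a, Cdh17, Dmbt1, Pigr, Cdh1, Krt8, Krt19 and Lypd8. Guca2a encodes guanylin and was at least 9435-fold lower, and Mep1a encodes a brush border protease and was at least 6701-fold lower (limma, adjusted p = 0.00225 and 0.00080). Krt8 and Krt19 are keratins of simple epithelia. Krt8 read 19.88 ± 0.01 in PBS, near the top of the scale, and 6.12 ± 2.14 in MBELN (SD, n = 3). Pigr, the receptor that carries immunoglobulin A across the epithelium, fell by 13.92 ± 1.33 (SE, n = 3). Guca2a and Mep1a fell by at least 13.20 and 12.71, against 13.58 for Lypd8, the last of the 12, and the PBS values of Krt8 and Pigr, 19.6 and above, lay near the top of the scale, and the MBELN means of Clca1 and Krt19 lay below the receptor level, so order and membership of the 12 are not settled. The falls of these 12 genes kept an adjusted p under 0.05 when any 1 array was left out. In the same MBELN arrays, the gut epithelial median differed from the PBS mean by -11.83 to -13.28 log2 units.

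**Figure D3:**
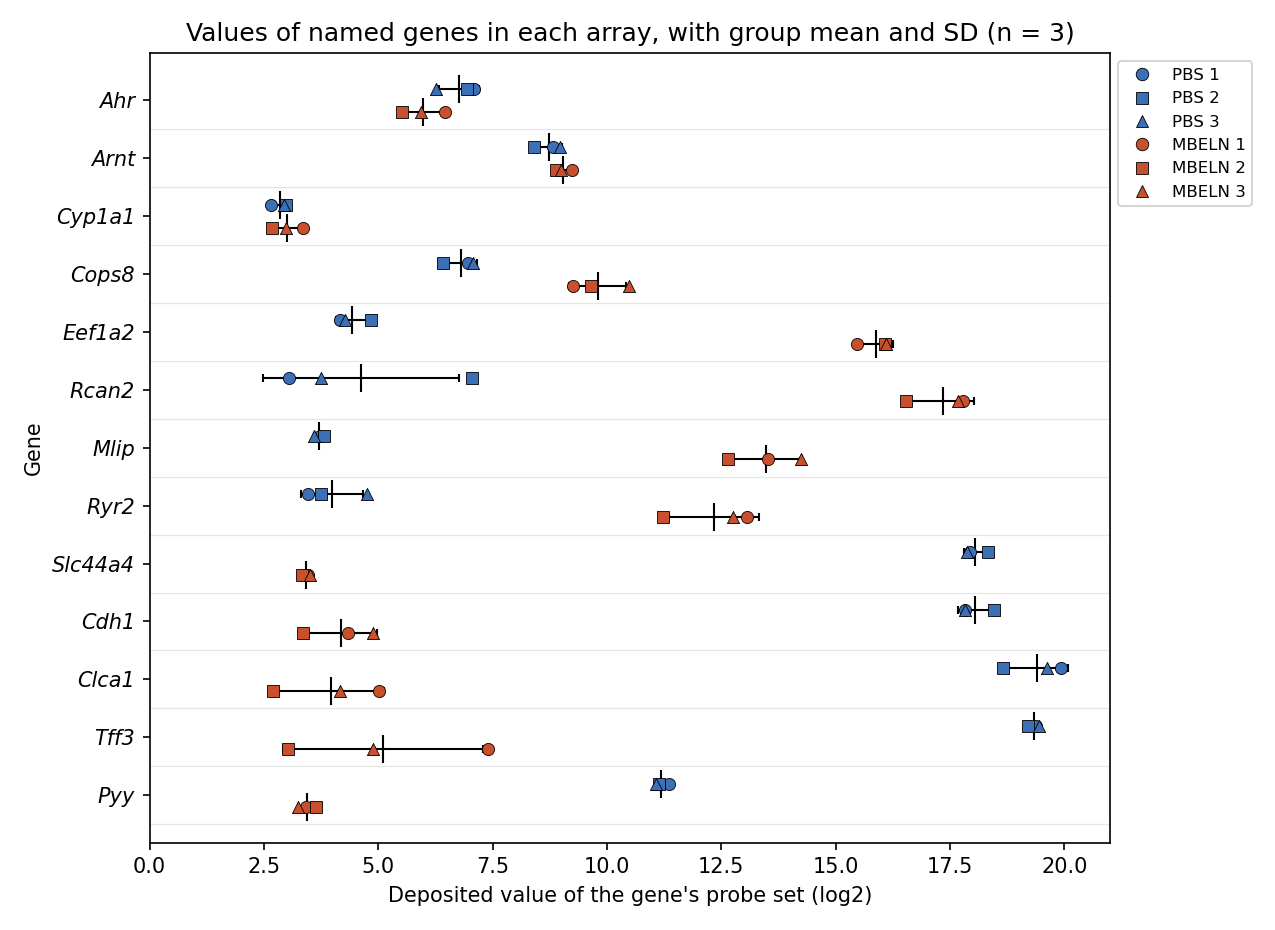
Deposited log2 value of 13 named genes in each array, with blue points for PBS, red points for MBELN, and circles, squares and triangles for replicates 1, 2 and 3. Black ticks and bars give the group mean and SD (n = 3), and Cops8 had all 3 MBELN values (9.26 to 10.49) above all 3 PBS values (6.41 to 7.07).

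By the same difference, the 12 named genes with the largest rises were Rcan2, Ptgds, Eef1a2, Ldhb, Mlip, Ak1, Coro6, Sorbs2, Pfkm, Qk, Ryr2 and Tmod1. Ldhb, the lactate dehydrogenase subunit of heart, rose by 10.23 ± 0.93 (log2, SE, n = 3) and Pfkm, the muscle form of phosphofructokinase, rose by 8.47 ± 0.77. Mlip, a lamin-interacting protein of muscle, was at least 631.8-fold higher (limma, adjusted p = 0.00080). Coro6 rose by at least 7.17, against 8.26 for Tmod1, the last of the 12, and the PBS means of Ptgds and Ryr2 lay below the receptor level, so order and membership are not settled here either. Ryr2 encodes a calcium release channel and rose from 3.98 ± 0.67 to 12.34 ± 0.98 (SD, n = 3). Ryr2 was also the single gene of the 15 heart muscle genes that passed the threshold, with 13.1, 11.2 and 12.8 in MBELN 1, 2 and 3. Ldhb, Pfkm and Mlip read 13.8, 12.8 and 12.6 in MBELN 2, where the heart muscle median was 3.68. Their rises therefore do not mark heart muscle in that array. The heart muscle list had a median shift of 9.04. The neuronal list had 0 of 13 genes past the threshold with limma, 1 of them with an unadjusted p under 0.05. Its median shift was 3.66, or 2.74 with genes below the receptor level in all 3 PBS arrays at their bound. No list test is given for either, since both were chosen after the values had been seen. Without PBS 1, the adjusted p was 0.0628 for Ptgds, 0.102 for Ak1, 0.0586 for Coro6, 0.0720 for Sorbs2 and 0.158 for Tmod1. Each of these 5 calls also ended without PBS 3, with 0.0552, 0.0985, 0.0573, 0.0661 and 0.167 in the same order. Those of Ptgds, Ak1, Sorbs2 and Tmod1 ended without MBELN 1 (0.0530, 0.0847, 0.0564 and 0.140), those of Ak1, Coro6, Sorbs2 and Tmod1 without MBELN 3 (0.0684, 0.0555, 0.0573 and 0.124), and that of Tmod1 without PBS 2 (0.0844).

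Of 20 measured goblet cell genes, whose products form the mucus layer, 16 fell, 0 rose and 4 did not pass the threshold, and 17 fell when adjusted over the list alone. Agr2, a mucin folding protein, was at least 1285-fold lower, and Muc2, the main gel-forming mucin, fell by 12.61 ± 1.02 (log2, SE, n = 3). Tff3, a trefoil peptide, fell by 14.24 ± 1.09 and Klk1, a kallikrein, fell from 17.55 ± 1.94 to 4.03 ± 0.54 (SD), a mean below the receptor level. The list's median shift was -3.41, or -2.67 with genes below the receptor level in all 3 MBELN arrays at their bound (camera, adjusted p = 2.44e-18, and adjusted p = 0.106 with an estimated correlation). Within the arrays of higher and of lower hybridisation control level the shift was -3.28 and -4.51, and it was -3.38 with the level as a block. The gut epithelial median differed from the PBS mean by -12.26, -13.28 and -11.83 in MBELN 1, 2 and 3.

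Tight junction genes, which seal the gaps between epithelial cells, had 12 of 19 measured members lower, 0 higher and 7 not past the threshold, and 13 lower when adjusted over the list alone. Cldn7 was at least 2115-fold, Cldn3 at least 493.5-fold, Tjp3 at least 197.6-fold and Cldn4 at least 148.7-fold lower. The first, second and last of these encode claudins, and Tjp3 encodes a scaffold protein of the junction. The median shift was -5.11, or -4.73 with bounds (camera, adjusted p = 5.58e-15). Of the 42 lists tested, this was the single list that passed with an estimated correlation (adjusted p = 0.0370). Its shift was -4.62 with the hybridisation control level as a block, and -3.74 and -5.70 within the arrays of higher and of lower level. Beside these genes, the gut epithelial median differed from the PBS mean by -11.83 to -13.28 in the MBELN arrays, where the heart muscle list (14.36 and 14.97 in MBELN 1 and 3) or the neuronal list (12.32 in MBELN 2) stood above it.

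Of 25 colonocyte genes, 8 fell, 0 rose and 17 did not pass the threshold, and 13 fell when adjusted over the list alone. Ceacam20, a cell adhesion molecule of the brush border, was at least 2141-fold lower. Cdhr5, a cadherin that links microvilli, fell by 12.43 ± 1.01 (log2, SE, n = 3). Krt20, a keratin of differentiated cells, fell by 12.08 ± 1.33, a call that ended without PBS 1 (limma, adjusted p = 0.0558) and without PBS 3 (0.0566). Colonocyte genes had a median shift of -6.82 (camera, adjusted p = 3.32e-11, and adjusted p = 0.106 with an estimated correlation), and -10.38 without PBS 2, the array in which colon-enriched genes had a median of 14.74. The shift was -6.70 with the hybridisation control level as a block, and -7.37 and -12.09 within the arrays of higher and of lower level. Of 23 mucin and glycosylation genes, 11 fell, 0 rose and 12 did not pass, and 16 fell when adjusted over the list alone. Galnt4 and Galnt3, which start mucin-type O-glycans, were at least 38.99-fold and 17.24-fold lower, and Gcnt3, which branches them, was at least 146.5-fold lower. The median shift was -4.30, or -4.11 with bounds (adjusted p = 2.28e-11, and adjusted p = 0.0668 with an estimated correlation), with -4.52, -4.31 and -3.82 in the same settings. Beside both lists, the gut epithelial median differed from the PBS mean by -11.83 to -13.28 in the MBELN arrays.

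Xenobiotic metabolism genes had 9 of 27 measured members lower, 0 higher and 18 not past the threshold, and 18 lower when adjusted over the list alone. Ces2a, a carboxylesterase, was at least 104.7-fold lower, and Abcb1a, a drug efflux pump, fell by 7.46 ± 0.56 (log2, SE, n = 3). Ugt2b34, a glucuronosyltransferase, fell from 15.34 ± 0.23 to 3.70 ± 1.37 and Nr1i2, the pregnane X receptor, from 9.77 ± 0.17 to 3.88 ± 0.65 (SD), with MBELN means below the receptor probe set level. For the whole list the shift was a median of -4.08, or -3.83 with bounds (camera, adjusted p = 4.34e-12, and adjusted p = 0.106 with an estimated correlation). It was -4.33 with the hybridisation control level as a block, and -3.48 and -6.13 within the arrays of higher and of lower level. For the gut epithelial median, the differences from the PBS mean in the MBELN arrays were -11.83 to -13.28. Of 21 antimicrobial and mucosal defence genes, 5 fell, 0 rose and 16 did not pass, and 5 fell when adjusted over the list alone. Lypd8, which keeps bacteria off the colonic surface, fell by 13.58 ± 1.04, and Duoxa2, the maturation factor of an epithelial oxidase, was at least 132.8-fold lower. The call of Duoxa2 ended without PBS 1 (limma, adjusted p = 0.0558) and without MBELN 3 (0.0643). The defence list had a median shift of -7.04, or -5.97 with bounds (adjusted p = 9.19e-05, and adjusted p = 0.382 with an estimated correlation). That shift was -5.74 with the hybridisation control level as a block, 0.29 within the arrays of higher level and -9.69 within those of lower level. List medians in PBS 1, 2 and 3 were 12.71, 3.96 and 13.81, beside Paneth cell medians of 19.06, 3.69 and 19.61.

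Of 14 small intestinal enterocyte genes, 1 fell, 0 rose and 13 did not pass the threshold, and 2 fell when adjusted over the list alone. Apob, the protein of chylomicrons, fell by 10.40 ± 1.66 (log2, SE, n = 3; limma, adjusted p = 0.0268), a call that ended without PBS 1 (0.129), PBS 3 (0.131) or MBELN 3 (0.0982). The median shift was -5.79 (camera, adjusted p = 0.00321, and adjusted p = 0.563 with an estimated correlation), and the call ended without MBELN 2 (adjusted p = 0.0979). That shift was -3.55 without PBS 1, -9.45 without PBS 2 and -3.60 without PBS 3. Of 10 Paneth cell genes, 0 passed with limma, 1 had an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. Ang4, an antimicrobial angiogenin, read 18.7, 3.94 and 18.8 in PBS 1, 2 and 3, and Lyz1, the Paneth cell lysozyme, read 19.4, 7.19 and 19.8. The Paneth cell shift was -9.08 (adjusted p = 0.000465, and adjusted p = 0.468 with an estimated correlation), and -14.00 without PBS 2. Within the arrays of higher and of lower hybridisation control level it was 0.90 and -15.42, and for enterocytes 1.21 and -13.35. With the level as a block, the shifts were -6.72 and -4.14.

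Ahr and the transcripts around it were named before the values were seen, and Ahr encodes the aryl hydrocarbon receptor, a sensor of plant and microbial compounds. Ahr read 6.76 ± 0.43 in PBS and 5.97 ± 0.48 in MBELN (log2, SD, n = 3), a difference of -0.80 ± 0.39 (SE; limma, adjusted p = 0.369). Its partner Arnt read 8.73 ± 0.30 and 9.04 ± 0.18 (adjusted p = 0.632). Cyp1a1, the receptor's classic target, lay below the receptor probe set level in both groups, at 2.86 and 3.0 (limma, adjusted p = 0.837), so no fold is given. Of 9 measured receptor targets, 0 rose, 1 fell and 8 did not pass the threshold, and 1 fell when adjusted over the list alone. Of these 9, 3 lay below the receptor probe set level in both groups, so their lack of a call says little. The gene that fell was Scin, an actin-severing protein, by 8.45 ± 1.34 (adjusted p = 0.0262). This call ended without PBS 1 (adjusted p = 0.121), PBS 3 (0.115), MBELN 1 (0.0857) or MBELN 3 (0.0998). Scin fell beside gut epithelial genes, whose median differed from the PBS mean by -11.83 to -13.28 in the MBELN arrays. Receptor targets had a median shift of -0.13 (camera, adjusted p = 0.563, and adjusted p = 0.845 with an estimated correlation), and it was 0.11 without PBS 2 and 0.14 without MBELN 2. It was -0.36 with the hybridisation control level as a block, and 0.20 and -0.48 within the arrays of higher and of lower level.

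Cops8, a subunit of the COP9 signalosome that removes NEDD8 from cullins, rose. It read 6.81 ± 0.35 in PBS and 9.80 ± 0.62 in MBELN (log2, SD, n = 3), a difference of 2.99 ± 0.42 (SE; limma, adjusted p = 0.0180). The difference was 3.06 with the hybridisation control level as a block, and 3.47 and 2.64 within the arrays of higher and of lower level. The call ended without PBS 1 (adjusted p = 0.0931), PBS 3 (0.0813) or MBELN 3 (0.0555). Among probe sets past the threshold, 836 changed by at least as much as Cops8, itself included. Of 10 measured COP9 subunits, 1 rose, 0 fell and 9 did not pass, and 1 rose when adjusted over the list alone. Cops9 differed by 2.23 ± 1.11 (SE, n = 3; adjusted p = 0.378) and Cops5, the catalytic subunit, by 1.04 ± 0.61 (adjusted p = 0.450). Without MBELN 2, both passed (adjusted p = 0.0247 and 0.0459). For the subunits as a list, the median shift was 0.92 (camera, adjusted p = 0.0212, and adjusted p = 0.382 with an estimated correlation). That call ended without PBS 2 (adjusted p = 0.0584), and the shift was 1.64 without MBELN 2. It was 0.79 with the hybridisation control level as a block, and 1.81 and 0.22 within the arrays of higher and of lower level. Heart muscle genes (18.22 and 18.83) or neuronal genes (16.12) stood high in each of the 3 arrays in which Cops8 was higher.

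Of 19 cullin and neddylation genes, 1 rose, 0 fell and 18 did not pass the threshold, and 1 rose when adjusted over the list alone. Cul7, a cullin, rose by 1.90 ± 0.34 (log2, SE, n = 3; limma, adjusted p = 0.0383), a call that ended without PBS 1 (0.125), PBS 2 (0.0621), PBS 3 (0.141), MBELN 1 (0.124) or MBELN 3 (0.135). Over the cullin list, the median shift was 0.60 (camera, adjusted p = 0.0195, and adjusted p = 0.382 with an estimated correlation). It was 0.96 without MBELN 2 and 0.31 without MBELN 3, where the call ended (adjusted p = 0.0920). With the hybridisation control level as a block it was 0.28, and 0.74 and 0.37 within the arrays of higher and of lower level. Of 16 heat shock and chaperone genes, 1 rose, 0 fell and 15 did not pass, and 1 rose when adjusted over the list alone. This was Stip1, a chaperone adaptor, at 2.19 ± 0.41 (adjusted p = 0.0444). Its call ended without PBS 1 (0.176), PBS 2 (0.0814), PBS 3 (0.125), MBELN 1 (0.0802) or MBELN 3 (0.155). The heat shock list did not pass (median shift 1.23, adjusted p = 0.125, and adjusted p = 0.427 with an estimated correlation), but it passed without MBELN 2 (shift 0.95, adjusted p = 0.0310). Leaving out MBELN 1 or MBELN 3 gave a shift of 0.78 or 0.58. Its shift was 0.93 with the block, and 1.30 and 0.26 within the arrays of higher and of lower level. In the same MBELN arrays, 1 of the heart muscle and neuronal lists stood over 12 log2 units above the PBS mean.

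Smooth muscle genes, which encode contractile proteins of the bowel wall, had 6 of 11 measured members lower, 0 higher and 5 not past the threshold, and 7 lower when adjusted over the list alone. Mylk, the myosin light chain kinase, fell by 8.24 ± 0.83 (log2, SE, n = 3). Actg2, the enteric smooth muscle actin, fell from 17.25 ± 0.75 to 4.08 ± 1.31 (SD), a mean below the receptor probe set level. The list medians were 14.30, 16.33 and 14.77 in PBS 1, 2 and 3, so transcripts of bowel wall muscle were abundant in the PBS arrays. Smooth muscle genes had a median shift of -8.24 (camera, adjusted p = 5.69e-08, and adjusted p = 0.427 with an estimated correlation), and -8.60 with the hybridisation control level as a block, -7.01 within the arrays of higher and -10.19 within those of lower level. Of 10 endothelial genes, 1 rose, 0 fell and 9 did not pass, and 1 rose when adjusted over the list alone. Flt1, a receptor for vascular growth factors, rose by 5.05 ± 0.91 (limma, adjusted p = 0.0392). The Flt1 call ended without PBS 1 (0.159), PBS 2 (0.0567), PBS 3 (0.158), MBELN 1 (0.139) or MBELN 3 (0.143). Kdr, another such receptor, read 4.94 in MBELN 2 and differed by 5.47 ± 2.04 (adjusted p = 0.245), and it passed without MBELN 2 (adjusted p = 0.00027). The endothelial median shift was 4.61 (adjusted p = 0.000295, and adjusted p = 0.468 with an estimated correlation). It was 3.06 with the block, and 5.17 and 0.53 within the arrays of higher and of lower level. The heart muscle medians of MBELN 1, 2 and 3 were 18.22, 3.68 and 18.83.

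Of 33 oxidative phosphorylation genes, 0 passed the threshold with limma, 3 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Ndufs1, a complex I subunit, read 9.92, 9.35 and 10.4 in PBS and 15.2, 10.7 and 15.5 in MBELN 1, 2 and 3 (limma, adjusted p = 0.208), and it passed without MBELN 2 (adjusted p = 0.000855). Across these genes the median shift was 2.86 (camera, adjusted p = 6.39e-05, and adjusted p = 0.601 with an estimated correlation), 4.80 without MBELN 2, 1.76 without MBELN 1 and 1.67 without MBELN 3. It was 1.66 with the hybridisation control level as a block, 4.87 within the arrays of higher level and -1.20 within those of lower level. The heart muscle medians of MBELN 1, 2 and 3 were 18.22, 3.68 and 18.83.

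Of 32 cell cycle genes, 1 fell, 0 rose and 31 did not pass the threshold, and 4 fell when adjusted over the list alone. Tyms, which makes thymidylate for DNA synthesis, fell by 2.72 ± 0.47 (log2, SE, n = 3; limma, adjusted p = 0.0346). Its call ended without PBS 1 (0.162), PBS 3 (0.119), MBELN 1 (0.132) or MBELN 3 (0.132). Cell cycle genes had a median shift of -2.11, or -1.39 with bounds (camera, adjusted p = 5.63e-10, and adjusted p = 0.468 with an estimated correlation). It was -1.84 with the hybridisation control level as a block, and -0.20 and -3.24 within the arrays of higher and of lower level. Of 19 crypt stem cell and Wnt target genes, 1 fell, 0 rose and 18 did not pass, and 3 fell when adjusted over the list alone. Prom1, a membrane protein of crypt base cells, fell by 6.06 ± 0.91 (adjusted p = 0.0227). The Prom1 call ended without PBS 1 (0.0949), PBS 3 (0.114), MBELN 1 (0.0821) or MBELN 3 (0.0978). The stem cell median shift was -0.93 (adjusted p = 0.00319, and adjusted p = 0.468 with an estimated correlation), with -0.86, -0.36 and -0.94 in the same settings. Paneth cell genes, also of the crypt base, had medians of 19.06, 3.69 and 19.61 in PBS 1, 2 and 3. Along with these lists, the gut epithelial median differed from the PBS mean by -11.83 to -13.28 in the MBELN arrays, the heart muscle median by 14.36 and 14.97 in MBELN 1 and 3, and the neuronal median by 12.32 in MBELN 2.

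Of 18 enteroendocrine genes, 2 fell, 0 rose and 16 did not pass the threshold, and 4 fell when adjusted over the list alone. Pyy, a gut hormone, was at least 117.6-fold lower (limma, adjusted p = 0.000493). Tph1, the first enzyme of serotonin synthesis in the gut, was at least 2.74-fold lower, a call that ended without PBS 1 (0.174), PBS 2 (0.0757), PBS 3 (0.180), MBELN 1 (0.0522) or MBELN 3 (0.150). The median shift was -1.02, or -0.68 with bounds (camera, adjusted p = 0.00435, and adjusted p = 0.382 with an estimated correlation). That shift was -0.66 without PBS 1, -0.55 without MBELN 1, -1.76 without MBELN 2 and -0.62 without MBELN 3. It was -0.49 with the hybridisation control level as a block, and -1.23 and -0.37 within the arrays of higher and of lower level. Of 19 cholesterol synthesis genes, 3 fell, 0 rose and 16 did not pass, and 7 fell when adjusted over the list alone. Ebp and Sc5d, late enzymes of the pathway, fell by 3.67 ± 0.42 and 4.83 ± 0.71 (log2, SE, n = 3). The call of Ebp ended without PBS 1 (0.0628) and PBS 3 (0.0610), and that of Sc5d without PBS 1 (0.110), PBS 3 (0.0938), MBELN 1 (0.0844) and MBELN 3 (0.0892). The cholesterol list's median shift was -2.97 (adjusted p = 2.93e-08, and adjusted p = 0.427 with an estimated correlation), with -2.27, -2.65 and -2.95 in the same settings. In the MBELN arrays, the gut epithelial median differed from the PBS mean by -11.83 to -13.28 log2 units.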

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

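The settings on the hybridisation control level and with PBS 2 and MBELN 2 both left out were chosen after seeing the data. The count of 1150 probe sets was 456 with the replicate block, 5757 with array weights, 3703 at an unadjusted p under 0.05 with at least 2-fold change and 1772 at an adjusted p under 0.1. It was 4174 and 7234 within the arrays of higher and of lower hybridisation controls, with 1 residual degree of freedom and a lone array, PBS 2 or MBELN 2, in 1 group, and 6769 with PBS 2 and MBELN 2 both left out. Leaving out 1 array gave 377 to 3738. Quantile normalization gave 1132, median centring 1161, the dim filter 1141, the trended robust model 865 and the hybridisation control block 1375. The 25 lists past the threshold became 1 with an estimated correlation and 12 with fry, and 23 to 28 when 1 array was left out. The array weights were 0.14 for MBELN 2 and 0.52 for PBS 2, and between 1.41 and 3.07 for the other arrays. That setting thus largely set MBELN 2 and PBS 2 aside. The looser thresholds raise the count by construction, and the cause of the other changes was not tested.

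Same-numbered arrays did not deviate from their group means together. The deviations carry the marker differences between arrays described above, so they cannot tell whether mice or batches were paired, and a pairing is not stated. Deviations of same-numbered arrays correlated at -0.03, -0.07 and -0.06, and PBS 1, 2 and 3 were closest to MBELN 2, 1 and 2. The replicate block left 25 lists past the threshold.

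Of 110 named genes, 109 kept direction and side of the threshold under quantile normalization, 110 under median centring, 77 under array weights, 90 under the replicate block and 104 under the hybridisation control block. With array weights, 33 newly passed and 0 calls ended. The replicate block ended 19 calls and added 1, and the hybridisation control block ended 1 and added 5. Leaving out 1 array ended up to 25 calls of the named genes. Cyp1a1 differed by -0.0307 without MBELN 1 and by up to 0.315 with another array left out. The shift of the aryl hydrocarbon receptor targets turned to 0.35 with array weights, 0.11 without PBS 2, 0.14 without MBELN 2 and 0.37 without PBS 2 and MBELN 2, and leaving out MBELN 1 gave -0.407. Of 50 leading genes and lists, 46 kept their sign within the arrays of higher and 47 within those of lower hybridisation controls. The 12 largest falls, the 12 largest rises and Cops8 had no overlap between groups, so their signs were fixed in advance. Only the lists, Ahr, Arnt and Cyp1a1 could change sign. Signal over background limits genes near the dim level, whose change is a bound only where every array of 1 group lay below its level.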

Other observations

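Of 22 measured vesicle and endosome genes, 3 fell, 1 rose and 18 did not pass the threshold, and 6 fell and 1 rose when adjusted over the list alone. Vps4b, an ATPase of membrane scission, fell by 3.83 ± 0.33, Cd82, a tetraspanin, fell by 7.71 ± 0.79, and Pdcd6ip, known as Alix, fell by 3.28 ± 0.41 (log2, SE, n = 3). Cd81, another tetraspanin, rose by 3.41 ± 0.47. The calls of Pdcd6ip and Cd81 ended without PBS 1 (limma, adjusted p = 0.0803 and 0.0844) and without PBS 3 (0.0702 and 0.0915), and that of Cd81 also without MBELN 1 (0.0821) and MBELN 3 (0.0841). The median shift was -1.35 (camera, adjusted p = 0.000623, and adjusted p = 0.382 with an estimated correlation). It was -1.51 with the hybridisation control level as a block, and -1.17 and -1.96 within the arrays of higher and of lower level. In the MBELN arrays, gut epithelial genes had a median that differed from the PBS mean by -11.83 to -13.28, and the heart muscle list (14.36 and 14.97 in MBELN 1 and 3) or the neuronal list (12.32 in MBELN 2) lay above that mean.

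Among 20 unfolded protein response genes, 2 fell, 0 rose and 18 did not pass, and 3 fell when adjusted over the list alone. Edem1, which directs misfolded proteins to degradation, fell by 5.21 ± 0.41 (log2, SE, n = 3). Among 20 NRF2 targets, 2 fell, 0 rose and 18 did not pass, and 5 fell and 2 rose when adjusted over the list alone. Txnrd1, a thioredoxin reductase, fell by 4.61 ± 0.33 and Pgd, of the pentose phosphate pathway, fell by 5.17 ± 0.39. The unfolded protein list had a median shift of -1.38 (camera, adjusted p = 0.000465, and adjusted p = 0.382 with an estimated correlation), and -0.87 without PBS 3. The NRF2 list had a shift of -0.15 (adjusted p = 0.0621, and adjusted p = 0.563 with an estimated correlation) and passed without MBELN 1 (adjusted p = 0.0207), without MBELN 3 (0.0421) and with the hybridisation control level as a block (-0.47, adjusted p = 0.0421). Its shift lay between -0.22 without PBS 2 and -0.49 without MBELN 2 when 1 array was left out. Within the arrays of higher and of lower level, the shifts were -0.24 and -1.93 for the unfolded protein list, with -0.92 in the block, and -0.71 and -1.88 for the NRF2 list. Beside both lists, the gut epithelial median differed by -11.83 to -13.28 in the MBELN arrays, with the heart muscle median up by 14.36 and 14.97 in MBELN 1 and 3 and the neuronal median by 12.32 in MBELN 2. Alb, which encodes serum albumin, read 17.6 in PBS 2 and between 5.08 and 7.37 in the other 5 arrays. Of 9 liver genes, a list chosen after the values had been seen, 1 fell, and the median was 10.02 in PBS 2 and between 3.64 and 5.82 in the other arrays. Of the other marker lists chosen after the values had been seen, skeletal muscle, kidney and lung genes had medians between 2.84 and 4.36 in all 6 arrays.

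The tests in the following 3 paragraphs, apart from the counts over other splits, were chosen after the results had been seen. For heart muscle transcripts in MBELN 1 and 3, more carry-over of bowel wall muscle than in PBS would raise smooth muscle genes. Their median differed from the PBS mean by -7.02 in the higher of these arrays. Smooth muscle medians were already 14.30, 16.33 and 14.77 in PBS 1, 2 and 3, and were 8.11 and 7.29 in MBELN 1 and 3. The fall therefore argues against more such muscle than in PBS, and cannot exclude a smaller amount. For neuronal transcripts in MBELN 2, carry-over of bowel nerve into crypts would leave epithelial genes near their PBS level. The gut epithelial median there differed by -13.28. These epithelial genes belong to the pattern itself, so their fall argues only against nerve added to crypts otherwise as in PBS. Enteric neuron and glia genes, a list fixed before, had a median of 7.50 in MBELN 2 and 3.99 to 4.35 in PBS. That list shares Snap25 and Gfap with the brain lists, so it cannot tell bowel nerve from brain. An effect of the treatment alike in all 3 arrays would raise heart genes in MBELN 2 too, but their median there differed by -0.17. That value restates the pattern and shows only that the MBELN arrays differ from each other. Effects that differ between the arrays stay open. RNA of other tissues in these columns is a candidate explanation that stays open, since the values that prompted it, such as a gut epithelial median that differed from the PBS mean by -11.83 in the array nearest to PBS, cannot also test it.

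Lower epithelial transcripts and higher Cops8 in the arrays labelled MBELN could come from the treatment or from a difference in tissue. Goblet cell medians in MBELN 1, 2 and 3 were 4.11, 3.70 and 3.92, under the receptor probe set levels of 4.39, 4.10 and 4.44. These arrays therefore held little goblet cell signal in which to read an effect on crypts. In 3 of 3 MBELN arrays, a tissue list from outside the gut stood over 8 log2 units above PBS, so an effect of the treatment on crypt epithelium cannot be told apart from a difference in tissue between these arrays. The 10 splits of the 6 arrays are too few for a share under 0.05. The labelled groups gave 1150 probe sets, as many as 1 of the 10 splits (itself), and the highest of the others gave 23. They gave 25 lists, a number that 2 of the 10 splits reached, and the highest of the others, with PBS 1, PBS 3 and MBELN 1 together, gave 26. Every other split gave at least 11 lists. The number of lists that pass camera at the preset correlation therefore does not mark out the labelled groups.

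Small intestinal transcripts in PBS 1 and 3 and colon transcripts in PBS 2 may come from different gut regions, which stays open, since the Paneth cell median, 15.37 higher in the lower of PBS 1 and 3 than in PBS 2, is among the values that prompted it. Small intestinal tissue mixed into colon crypts would leave colon-enriched genes high, and their median in the higher of PBS 1 and 3 differed from PBS 2 by -11.35. That list too was chosen after these values had been seen, so its median cannot test such a mixture, which stays open. Of the list, Car4 read 14.8 and 14.7 and Slc26a3 10.5 and 11.3 in PBS 1 and 3, against 19.1 and 17.5 in PBS 2. Retnlb, of the same list, went the other way, with 8.10 in PBS 1 and 2.30 in PBS 2. Cdx2, an intestinal transcription factor, read 3.45 in PBS 2 and 12.3 and 12.9 in PBS 1 and 3, and the liver gene Alb read 17.6 in PBS 2. The labels give colon crypt for all 3 arrays and name no difference between them.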
